A study of Mus musculus with 12 samples.

How the data were processed

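RNA of 12 mouse ES-cell-derived samples was measured on Affymetrix arrays. Per the labels' protocols, total RNA was treated with DNase, and 5 ng of it was amplified and labelled with biotin by a NuGEN Ovation kit, with Affymetrix polyA controls added to follow the reaction. Per the submitters' processing notes, the authors processed the arrays with RMA (background correction, quantile normalization and a summary per probe set); the version is not given in the sources used here. The deposited values are on a log scale taken as log2, because RMA is defined on it; the notes do not name the base, and a largest range of 7.37 over the arrays for any probe set rules out log10. The deposited table holds 45101 probe sets, and each is centred: its median over the 12 arrays is 0 within 5e-07. No source used here mentions that centring. The values therefore carry differences between arrays and no level, and the medians of the 12 columns ran from -0.01 to 0.01. Scanner files were not analysed here, so neither the direction nor the scale could be set against raw signals; the direction is taken as larger for more RNA.

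Probe sets were named from the platform's annotation table, which dates from an older release. Leaving out 64 control probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had none; the gene numbers of 34741 probe sets were found in a RefSeq gene table of GRCm38.p6, and 0 symbols changed. No coordinates are given, since the sources name no build. Where a listed gene is not named by a probe set here, it was not analysed.

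Centred values still show roughly how bright a probe set was. They are differences of single-precision numbers, and the spacing of values above the median shows in which power of 2 the median level lay. By this reading 20.0% of probe sets had a median log2 level of at least 8, 40.3% of 4 to 8, 34.8% of 2 to 4 and 4.8% under 2. In 20000 simulated probe sets the reading gave the right class for 97.4% and a class too high for 2.6%. In a first version of this reading, 8190 probe sets had come out with no class because of digits rounded in the text. The correction was made after counts from the first version had been seen, for that reason alone, and the earlier counts are given with the alternatives.

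The plan made before the data were examined had a filter on dim genes and took each gene's brightest probe set, which centred values do not allow. In place of these, no gene was filtered out, and each of 18193 genes was given the mean of its probe sets in its highest level class; this was decided before any comparison was computed. The fit was limma 3.58.1 in R 4.3.3, with a mean per group over all 12 arrays, contrasts, moderated tests (eBayes) and Benjamini-Hochberg adjustment within each comparison at adjusted p 0.05. All groups share an estimate of the spread, with 6 residual and 3.59 prior degrees of freedom. Samples were grouped by the cell line, day and Dox treatment in the labels. The 7 comparisons were the Dox response of rtTA-Dmrt5 cells at day 7 and at day 9, that of rtTA cells at day 7, the differences between lines and between days in that response, day 9 minus day 7 without Dox, and rtTA-Dmrt5 minus rtTA without Dox. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 read the table and drew the plots.

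The fit was tested on simulated data for the day 7 Dox response, with the measured spread of 18193 genes. Of 100 genes changed by a log2 size of 1, 95 passed, and of 100 changed by 0.5, 25 passed, all in the right direction; 10 of 17993 unchanged genes passed. Smaller changes are therefore often missed at 2 arrays per group.

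Genes were named by a rule fixed before the data were examined. Dmrta2 comes first in every group. For each Dox response of rtTA-Dmrt5 cells, the 12 largest increases and 12 largest decreases are named among genes past adjusted p 0.05 whose replicates do not overlap between groups; for other comparisons 6 and 6. Where fewer than 5 genes pass, the 5 with the smallest p are given as values. Any member of a fixed list that passed may be named. With 2 arrays against 2, chance alone separates 33.3% of genes, and all 1262 and 5136 genes past the threshold at day 7 and day 9 had separate replicates. The 29 lists of marker, pathway and control genes were fixed at the same time and tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 29 lists within a comparison. Adjusted values in the text come from camera unless stated. Lists share some genes, such as Olig2, Isl1 and Gad2.

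Of camera's calls, 4 of 12 held with an estimated correlation for the day 7 response, 0 of 11 for day 9, 0 of 3 for the parental line, 8 of 10 for the difference between lines, 0 of 6 for the difference between days, 2 of 11 for day 9 minus day 7 and 3 of 7 between the lines. In fry, which asks whether a list's genes move on balance in a direction and compares them with no other genes, 16, 23, 0, 13, 11, 21 and 17 of 29 lists passed in that order. Alternatives covered the probe sets per gene, the scaling of arrays, the variance model, array weights, the arrays fitted, a fold threshold, the replicate number as a block, single arrays left out, and filters on the recovered level.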

Results

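Mouse embryonic stem (ES) cells were turned towards a neural fate as a monolayer in serum-free N2B27 medium, and their RNA was measured on 12 Affymetrix arrays. The cells came from a line called rtTA-Dmrt5, in which doxycycline (Dox) switches on a Dmrt5 transgene through the rtTA activator, and from its parental rtTA line, which carries no such transgene by its name. Dmrt5 is another name of Dmrta2, a transcription factor of the doublesex and mab-3 related family that acts in the developing cortex and midbrain. Dox was given from day 5 of differentiation, and cells were harvested at day 7 or day 9. The 12 samples form 6 groups of 2: rtTA at day 7 without and with Dox, rtTA-Dmrt5 at day 7 without and with Dox, and rtTA-Dmrt5 at day 9 without and with Dox. The parental line was measured at day 7 only, so the Dox response at day 9 has no parental measure of what Dox does by itself. The values tested cover 18193 genes. Each value is a difference from that probe set's median over the 12 arrays, so it can be compared between groups but gives no expression level. Changes are given as log2 fold changes ± standard error (SE) from limma, with n = 2 arrays in each group, and their number limits the precision. The labels do not say that replicates were separate cultures, so p-values measure the spread between these samples, which can be technical.

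The gene that the transgene carries was examined first, because it checks the labels. Dmrta2 has 1 probe set on the array, and its values were lower, not higher, in the rtTA-Dmrt5 arrays labelled +Dox. The change was -2.42 ± 0.33 at day 7 (adjusted p = 0.00196) and -2.61 ± 0.33 at day 9 (adjusted p = 0.000494). In the parental line it was 0.10 ± 0.33 (adjusted p = 0.987). Without Dox, the probe set was higher in rtTA-Dmrt5 than in rtTA at day 7, by 1.92 ± 0.33 (adjusted p = 0.00221). Which part of the transcript the probe set reads, and whether the transgene holds that part, is not given in the sources used here; a probe set outside the transgene reads only the cell's own gene and checks nothing. Because the measured direction goes against the label, groups are called "arrays labelled +Dox" and "arrays labelled -Dox", and every direction given for a Dox response rests on these labels. The plot of values per array sets Dmrta2 beside 5 other genes.

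**Figure D1:**
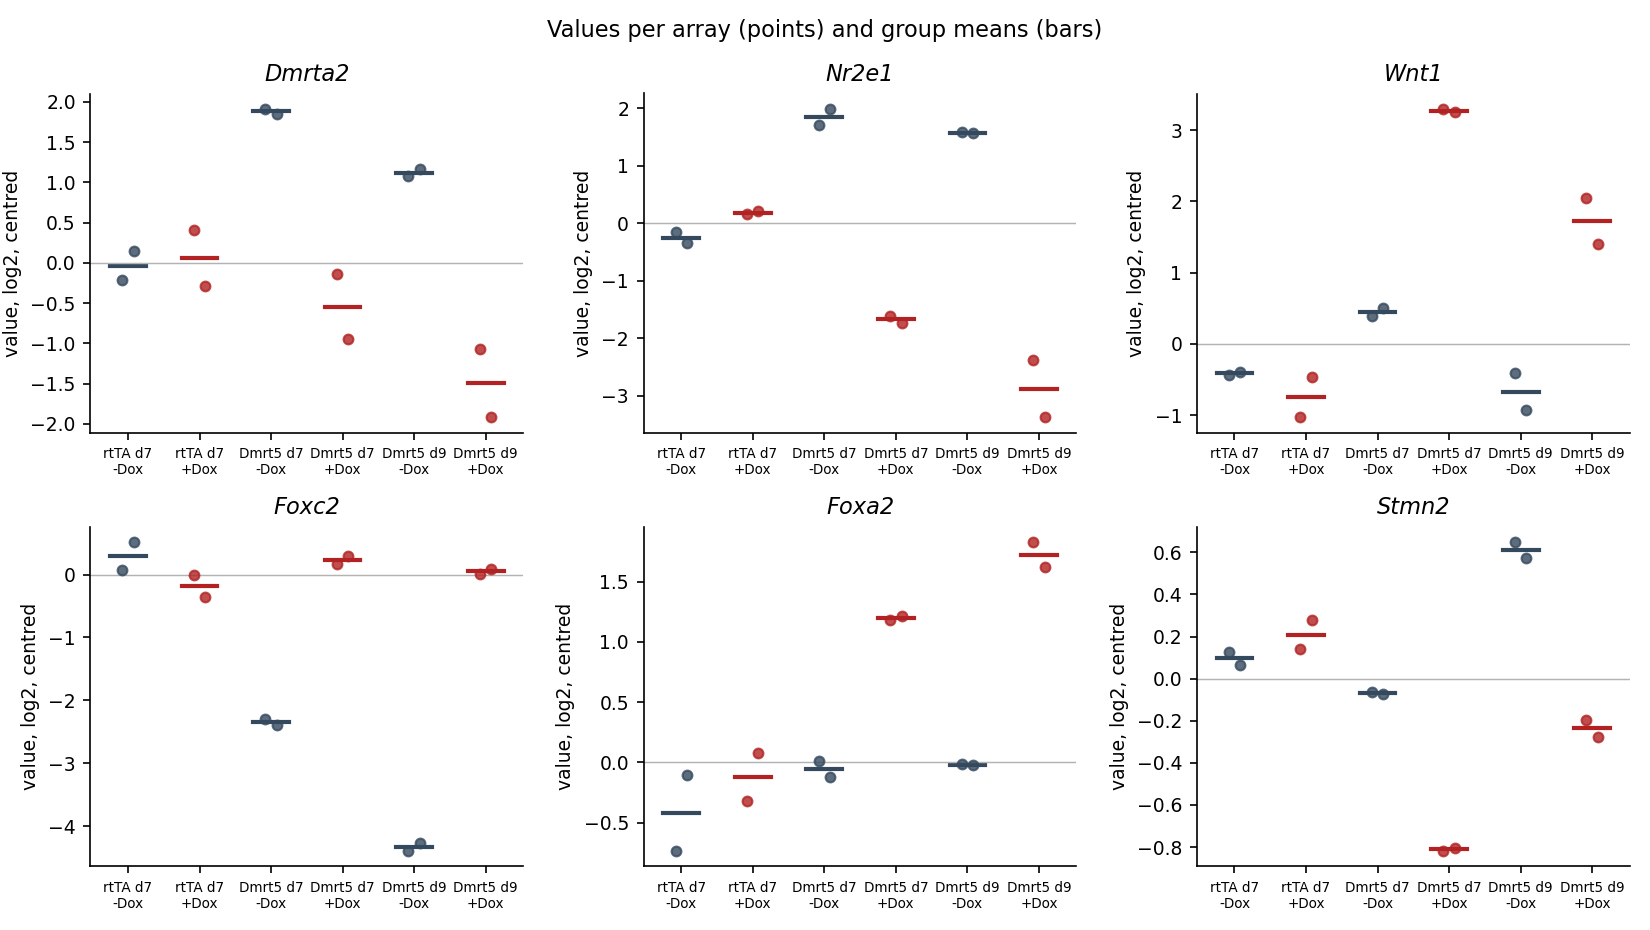
Values of 6 genes in each of the 12 arrays, in log2 units centred per probe set (vertical axis), for the 6 groups (horizontal axis; rtTA is the parental line, Dmrt5 the rtTA-Dmrt5 line); points are arrays, bars are group means, and red marks arrays labelled +Dox. Dmrta2 lies at 1.91 and 1.85 in the rtTA-Dmrt5 day 7 arrays labelled -Dox and at -0.14 and -0.95 in those labelled +Dox.

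At day 7 in rtTA-Dmrt5 cells, the arrays labelled +Dox were compared with those labelled -Dox to ask which genes respond to induced Dmrt5. Nr2e1, a nuclear receptor of forebrain neural stem cells, fell by 3.52 (SE 0.25), and Mab21l2 and Mab21l1, related genes of eye development, fell by 3.33 and 3.19. Dmrta1, a close relative of Dmrta2, fell by 2.49, and the AP-2 family factor Tfap2d by 2.66. Falls were also measured in Wfdc1 (-3.15), Ndnf (-2.93), the collagen Col3a1 (-2.79) and the neuropeptide precursor Cartpt (-2.48). The largest rises included Wnt1, a secreted factor of the midbrain-hindbrain boundary (2.83 ± 0.24), the forkhead factor Foxc2 (2.58 ± 0.16), the sodium channel gene Scn11a (2.60 ± 0.19) and Fgf18 (1.85 ± 0.14). The other genes taken by the naming rule were Gm3764 (3.15, with 1 of its probe sets at -0.19, and 2 at -0.21 and -0.34 at day 9), Defa31 (2.59), Islr (2.47), Pcp4 (2.41), Hlf (2.32), Rab37 (2.31), Krtap17-1 (2.28) and Nepn (1.87) among the rises, and Gm20083 (-3.22), Pdzph1 (-2.89) and Adgrv1 (-2.64) among the falls. Defa31 belongs to a family of near-identical defensin genes, and its probe set may read relatives. In all, 1262 of 18193 genes passed adjusted p 0.05 in limma, 562 higher and 700 lower in the arrays labelled +Dox. Of them 328 changed at least 2-fold, 100 higher and 228 lower. The count is unstable at this number of arrays, where leaving any array out also lowers power. It was 618 or 550 without replicate 1 or 2 of the arrays labelled -Dox, 637 or 521 without replicate 1 or 2 of those labelled +Dox, and 2355 with array quality weights. With these weights the balance turned to 1206 higher and 1149 lower. The weights came out equal within each group, at 1.35 for these arrays labelled -Dox and 1.48 for those labelled +Dox. They therefore weigh groups and do not rate single arrays.

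Pan-neuronal and ventral telencephalon genes fell as lists at day 7. Of 17 measured pan-neuronal genes, 11 fell and none rose, among them the neurofilament genes Nefm (-1.61) and Nefl (-1.23), the early neuronal factor Nhlh1 (-1.67) and the microtubule regulator Stmn2 (-0.74). The list's shift passed the camera test (adjusted p = 5.47e-14; adjusted p = 0.0442 with an estimated correlation), and adjusted over the list alone 15 members were lower and 1 higher. Of 15 ventral telencephalon genes, 6 fell and none rose, such as Gsx1 (-2.38), Isl1 (-1.72) and Sp8 (-1.27); camera gave adjusted p = 6.76e-06, and adjusted p = 0.0442 with an estimated correlation, with 9 lower adjusted over the list alone. Of 17 cortex genes 8 fell, including Nr2f1 (-1.97), Lhx2 (-1.65), Emx2 (-0.81) and Pax6 (-0.71), and none rose (camera adjusted p = 4.69e-05, adjusted p = 0.0594 with an estimated correlation; 8 adjusted over the list alone). The 8 measured Dmrt family genes held 4 that fell, Dmrta1, Dmrta2, Dmrt3 (-1.17, with 1 of its probe sets at 0.04) and Dmrt1 (-1.30) (camera adjusted p = 1.01e-06, adjusted p = 0.0467 with an estimated correlation; 6 lower adjusted over the list alone). Of 13 neural crest genes 5 fell, led by Pax3 (-1.74) (adjusted p = 0.0101, adjusted p = 0.0704 with an estimated correlation; 5 lower and 2 higher adjusted over the list alone).

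ES-cell markers rose as a list at day 7. Epithelium and placode genes did so in camera with the preset correlation and in the rotation test fry (adjusted p = 0.000995), but not with an estimated correlation. Of 16 undifferentiated ES-cell markers, 9 rose and none fell, including the pluripotency factor Pou5f1 (0.80) and Zfp42 (0.95) (camera adjusted p = 2.33e-07, adjusted p = 0.0442 with an estimated correlation; 12 higher adjusted over the list alone). Of 13 surface epithelium and placode genes 7 rose and none fell, such as the keratin genes Krt7 (1.45) and Krt19 (0.98) (adjusted p = 1.01e-06, adjusted p = 0.0548 with an estimated correlation; 8 higher adjusted over the list alone). Of the 15 mesoderm and endoderm genes only Apoa1 (0.88) rose, also adjusted over the list alone, while the list passed camera at adjusted p = 0.0199 and lost the call at adjusted p = 0.0854 with an estimated correlation. Of 17 cell cycle genes 2 rose, Ccne1 (0.43) and Aurka (0.37) (camera adjusted p = 0.000609, adjusted p = 0.0594 with an estimated correlation; 5 higher adjusted over the list alone). Of the 14 Bmp targets 4 rose and 1 fell (adjusted p = 0.0347, adjusted p = 0.107 with an estimated correlation; 5 higher and 2 lower adjusted over the list alone). Glia (3 of 11 fell) and neurotransmitter genes of GABAergic, glutamatergic, serotonergic and motor neurons (2 of 12 fell) each passed at adjusted p = 0.0495 and not with an estimated correlation, at adjusted p = 0.135 and adjusted p = 0.411; adjusted over the list alone the counts were again 3 and 2.

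The midbrain lists split at day 7. Of 19 ventral-medial (floor plate) midbrain genes 5 rose and 4 fell (9 and 4 adjusted over the list alone): the floor plate factor Foxa2 (1.25 ± 0.19), Wnt1, Wnt5a (0.72), Ntn1 (0.66, with 1 of its probe sets at -0.21) and Msx2 (0.43) rose, and Rspo2 (-1.77, with 1 of its probe sets at 0.050), the signal Shh (-1.02), Slit2 (-0.82) and Otx2 (-0.39) fell. Of 15 dopaminergic genes 2 rose and 2 fell (2 and 2 adjusted over the list alone): En1 (1.2) and Dlk1 (1.26) were higher, En2 (-2.0) and Th (-1.79), the rate-limiting enzyme of dopamine synthesis, lower. Of 18 ventral-lateral midbrain genes 5 fell, among them Olig2 (-1.68) and Pou4f1 (-1.08), and 2 rose (7 and 5 adjusted over the list alone). None of these 3 lists passed camera, at adjusted p = 0.214, 0.552 and 0.193. The other lists did not pass camera either. Rising and falling members numbered 3 and 3 of 18 for cortical hem, 2 and 2 of 10 for hypothalamus and eye field, 3 and 2 of 16 for hindbrain and Hox, 4 and 5 of 15 for neural progenitors, and 2 and 2 of 13 for mesenchyme. They numbered 2 and 1 of 11 for Shh targets, 5 and 2 of 14 for Wnt targets, 3 and 2 of 14 for Notch, 3 and 1 of 10 for retinoic acid, and 3 and 3 of 12 for Fgf targets. They numbered 1 and 1 of 13 for immediate early genes, and 0 and 0 for the 14 cell cycle inhibitors and p53 targets, the 15 integrated stress response genes and the 9 respiratory chain genes. Sp5, a Wnt target (1.70), and Dusp6, an Fgf target (-1.69), were the largest changes in their lists together with Fgf18. Adjusted over the list alone, the rising and falling counts were 4 and 4, 2 and 2, 3 and 2, 4 and 6, and 2 and 3 in the first sentence's order, then 2 and 1, 5 and 3, 4 and 2, 3 and 3, and 4 and 4, then 1 and 1 and again 0.

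**Figure D2:**
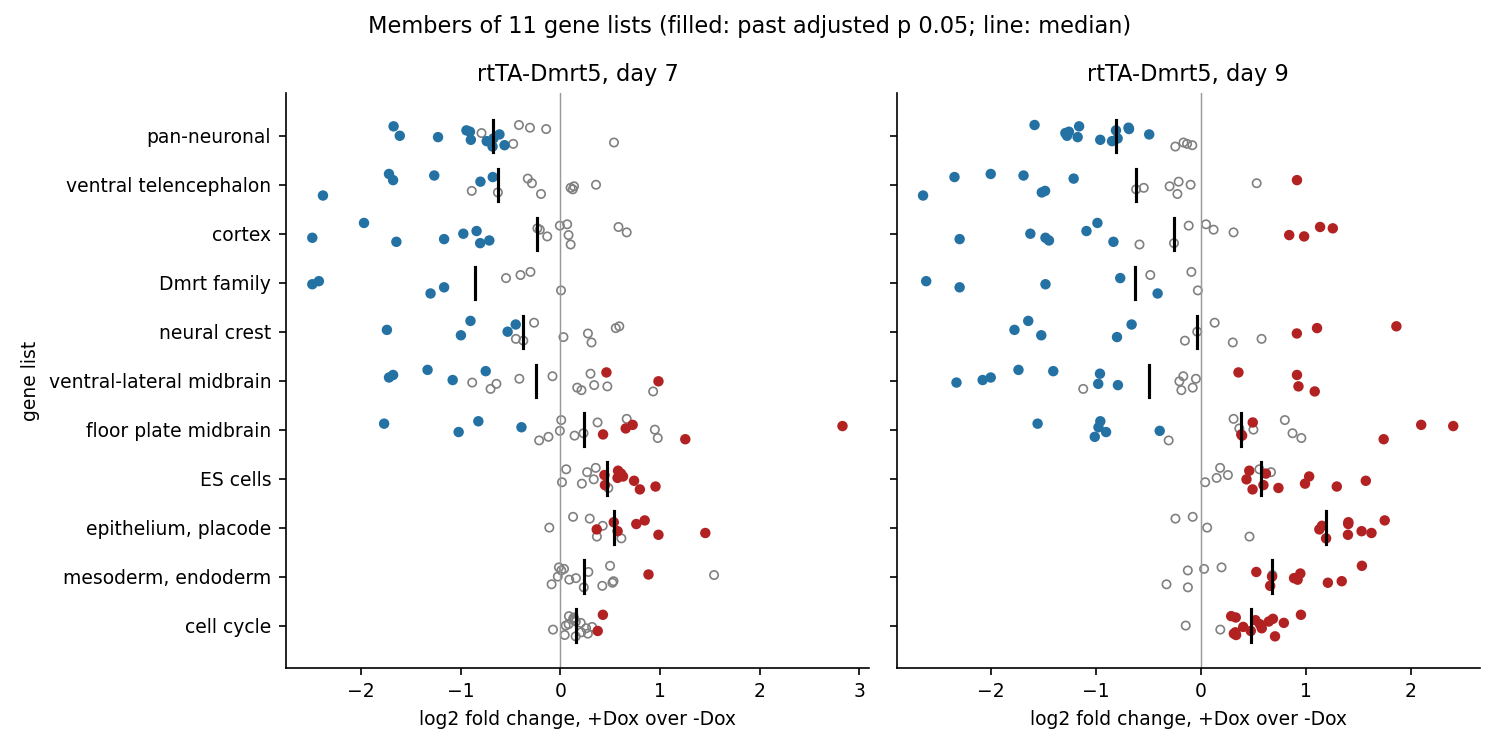
Log2 fold change of each measured member of 11 gene lists (rows) in arrays labelled +Dox over those labelled -Dox (horizontal axis, log2 units), at day 7 (left) and day 9 (right) in rtTA-Dmrt5 cells; filled points passed adjusted p 0.05 (red higher, blue lower), open points did not, and the vertical line is the list's median. The pan-neuronal median lies at -0.68 at day 7 and -0.81 at day 9, and that of epithelium and placode at 0.54 and 1.19.

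The parental rtTA line at day 7 measures what Dox does without the transgene, but in cells that already differed without Dox. Between the lines 5209 genes passed in arrays labelled -Dox, so what Dox by itself does in rtTA-Dmrt5 cells was not measured. In the parental Dox response no gene passed the threshold in limma. There 928 genes had an unadjusted p under 0.05, against 910 expected by chance. Without replicate 2 of the arrays labelled -Dox, 1 gene passed, and also 1 with the replicate number as a block within line and day. The smallest p-values belonged to Slc1a6 (0.92, adjusted p = 0.248), Dab2 (-1.36, adjusted p = 0.248), Gm4961 (0.57), Kcnq5 (0.83) and Foxa3 (0.67), given as values only. None of 15 integrated stress response genes, which can answer to Dox itself, passed, and their median change was 0.01. Hindbrain and Hox genes, mesoderm and endoderm genes and cell cycle genes were lower as lists with camera's preset correlation (adjusted p = 0.0478, 0.0084 and 0.0126), with 0 members past the threshold in each; adjusted over the list alone 1 mesoderm and endoderm gene was lower, and 1 Dmrt gene was higher. None of the 3 held with an estimated correlation (adjusted p = 0.39, 0.24 and 0.353). Hybridisation spike-ins, added in the same amount to every array, differed by -0.29 between arrays labelled +Dox and -Dox in this line and by -0.32 in rtTA-Dmrt5 at day 7 (pooled SD 0.13).

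The difference between the lines' Dox responses at day 7 was tested directly. It passed for 512 genes, 156 more positive and 356 more negative in rtTA-Dmrt5 (79 and 222 at 2-fold). The lines also differed without Dox, so the test does not isolate the transgene. The largest positive differences were in Srgn (3.27 ± 0.70), Wnt1 (3.16 ± 0.34), Foxc2 (3.06), Gm3764 (2.88), Defa31 (2.28) and Scn11a (2.25). For Srgn the parental change was -2.46 (adjusted p = 0.502) and that in rtTA-Dmrt5 0.81 (adjusted p = 0.407), and neither passed. The largest negative ones were in Nr2e1 (-3.96 ± 0.36), Gm20083 (-3.40), Mab21l2 (-3.36), Wfdc1 (-3.34), Mab21l1 (-3.17) and Col3a1 (-3.08). All 24 genes that the rule names for the day 7 response passed this test, and their parental changes ran from -0.48 to 0.43. These genes were chosen for the largest day 7 changes, and the test uses the same rtTA-Dmrt5 arrays, so their passing is no separate support. As lists, pan-neuronal, ventral telencephalon, cortex, Dmrt family and neural crest genes were more negative, and ES-cell, mesoderm and endoderm and cell cycle genes more positive, in rtTA-Dmrt5. Members past the threshold numbered 7, 6, 5, 4 and 3 among the more negative lists and 1, 1 and 0 among the more positive ones. Adjusted over the list alone they numbered 13, 7, 9, 5 and 4, and 8, 4 and 8, with 1 cortex gene and 1 neural crest gene going the other way. These 8 lists passed with the preset and with an estimated correlation, the latter at adjusted p between 0.0385 and 0.0467; epithelium and placode and neurotransmitter genes lost the call (adjusted p = 0.0738 and 0.322). The count was 322 with the replicate number as a block within line and day. Without either parental array labelled +Dox it stayed within 1.5 times of 512, and without any other day 7 array it fell further. Leaving any array out also lowers power, so these falls do not single out particular arrays.

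At day 9 the same comparison in rtTA-Dmrt5 cells covers 4 days of Dox. Foxc2 rose by 4.38 ± 0.16, the keratin-associated gene Krtap17-1 by 4.08 ± 0.15, the Wnt inhibitor Wif1 by 2.95 ± 0.15 and Inhbb, an activin subunit, by 2.86 ± 0.13. Foxc2 lay no higher in the arrays labelled +Dox at day 9 (0.01 and 0.09) than at day 7 (0.17 and 0.30). Its larger difference came with lower values in those labelled -Dox, at -4.391 and -4.267 against -2.305 and -2.395 at day 7. Parental arrays labelled -Dox lay at 0.07 and 0.51. Nr2e1 fell by 4.46 (SE 0.25), and so did the homeobox genes Shox2 (-3.98) and Otx1 (-3.82), the forkhead gene Foxn4 (-3.37), Tfap2d (-3.08), the retinoic acid degrading enzyme Cyp26b1 (-3.03), Ndnf (-2.81) and the glycine receptor gene Glra1 (-2.69). The rule further names Ddn (3.62), Islr (3.41), Cntn6 (2.84), 3110039M20Rik (2.69), Aldh1a7 (2.66), Fgf18 (2.62), Pla2g7 (2.60) and Scn11a (2.56) as rises, and Gm38604 (-3.51), G630016G05Rik (-3.32), Mxra7 (-3.02) and Ndst3 (-2.89) as falls. Aldh1a7 is a near copy of Aldh1a1, and its probe set may read both. In all 5136 genes passed, 3076 higher and 2060 lower in the arrays labelled +Dox. Of them 800 changed at least 2-fold, 464 higher and 336 lower. The count was 3065 without replicate 1 of the arrays labelled -Dox and 3175 when only these 4 arrays were fitted. It was 2871 with a recovered level of at least 8, and 7774 probe sets passed on their own. The arrays labelled +Dox at day 9 also stood apart in some control probe sets. Hybridisation spike-ins differed by -0.81 from those labelled -Dox (pooled SD 0.13). The 3' minus 5' difference of Actb, a measure of RNA integrity, was 0.21 ± 0.02 (SD) against -0.02 ± 0.04 (SD). The polyA controls lay closer together, at a mean of -0.026 ± 0.014 (SD) in arrays labelled +Dox and 0.016 ± 0.067 (SD) in those labelled -Dox.

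As lists, neuronal genes were lower and epithelial and cell cycle genes higher at day 9 with camera's preset correlation. None of these calls held with an estimated correlation. The arrays compared are those that differ in some of the control values above. Of 17 pan-neuronal genes 13 fell and none rose, among them Syt4 (-1.58), Snap25 (-1.29) and Syt1 (-1.25, with 1 of its probe sets at 0.025), genes of vesicle release (camera adjusted p = 2.63e-09, adjusted p = 0.0647 with an estimated correlation; 14 lower adjusted over the list alone). Of 12 neurotransmitter genes 6 fell, such as Gad2 (-2.34) and Gad1 (-1.21), the enzymes of GABA synthesis (adjusted p = 0.00068, adjusted p = 0.181 with an estimated correlation; 6 adjusted over the list alone). Of 18 ventral-lateral midbrain genes 8 fell, including Tal1 (-2.33), Pou4f1 (-2.08), Isl1 (-2.0) and Ptf1a (-1.74), and 4 rose, namely Nkx6-1 (1.08), Sim1 (0.93, with 1 of its probe sets at -0.11), Olig2 (0.92) and Lhx5 (0.36) (adjusted p = 0.00321, adjusted p = 0.133 with an estimated correlation; 9 lower and 4 higher adjusted over the list alone). Of 15 ventral telencephalon genes 7 fell, such as Dlx1 (-1.51) and Dlx2 (-1.48), and 1 rose (adjusted p = 0.000102, adjusted p = 0.0543 with an estimated correlation; 9 and 2 adjusted over the list alone). Of 8 Dmrt genes 5 fell (adjusted p = 0.00068, adjusted p = 0.0991 with an estimated correlation; 6 adjusted over the list alone).

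Of 13 epithelium and placode genes 9 rose at day 9 and none fell, including Epcam (1.53), the E-cadherin gene Cdh1 (1.13) and Krt8 (1.19) (camera adjusted p = 1.14e-05, adjusted p = 0.0647 with an estimated correlation; 10 adjusted over the list alone). Of 16 ES-cell markers 10 rose, including Zfp42 (1.29) and Tbx3 (1.57, with its dimmer probe sets between -0.0145 and -0.00812) (adjusted p = 3.46e-05, adjusted p = 0.0647 with an estimated correlation; 13 adjusted over the list alone). Of 15 mesoderm and endoderm genes 9 rose, such as Dab2 (1.53), Gata6 (1.34, with 1 of its probe sets at -0.25) and Gata4 (1.21), which mark primitive endoderm (adjusted p = 0.00178, adjusted p = 0.0647 with an estimated correlation; 9 adjusted over the list alone). Of 17 cell cycle genes 15 rose, by 0.29 (Pcna) to 0.95 (Ccne1), with Mki67 at 0.71 (adjusted p = 6.24e-07, adjusted p = 0.0543 with an estimated correlation; 15 adjusted over the list alone). Of 12 Fgf targets 6 rose and 1 fell, with Fgf18, Il17rd (1.72) and Fgf17 (1.48) in front (adjusted p = 0.00321, adjusted p = 0.143 with an estimated correlation; 6 and 2 adjusted over the list alone). Of 14 Bmp targets 9 rose, including Bmp7 (1.27) and Id3 (1.15), and 1 fell (adjusted p = 0.0125, adjusted p = 0.0991 with an estimated correlation; 9 and 1 adjusted over the list alone). The 11 lists that passed camera at day 9 therefore all lost the call with an estimated correlation.

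The remaining lists did not pass camera at day 9. Of 19 floor plate genes 6 rose and 6 fell (8 and 6 adjusted over the list alone). Foxa2 (1.74 ± 0.19), Wnt5a (2.10) and Wnt1 (2.40) were higher, and Rspo2 (-1.55), Lmx1b (-1.01), Otx2 (-0.97) and Shh (-0.90) lower. Of 15 dopaminergic genes 4 rose and 3 fell (4 and 3 adjusted over the list alone), with Calb1 at -2.36, En2 at -1.77 and Drd2 at 0.73. Rising and falling members numbered 4 and 7 of 17 for cortex, 4 and 7 of 18 for cortical hem, 1 and 3 of 10 for hypothalamus and eye field, 6 and 1 of 16 for hindbrain and Hox, 3 and 6 of 15 for neural progenitors, 1 and 1 of 11 for glia, 3 and 5 of 13 for neural crest, and 5 and 1 of 13 for mesenchyme. They numbered 6 and 1 of 11 for Shh targets, where Cdon, a receptor component, rose by 2.38, 6 and 4 of 14 for Wnt targets, 5 and 4 of 14 for Notch and 4 and 2 of 10 for retinoic acid. They numbered 4 and 1 of 14 for cell cycle inhibitors and p53 targets, 2 and 3 of 15 for integrated stress response, 3 and 0 of 13 for immediate early genes and 2 and 0 of 9 for the respiratory chain. Adjusted over the list alone the counts were 4 and 8, 6 and 8, 2 and 3, 7 and 1, 3 and 6, 1 and 1, 4 and 5 and 5 and 1 in the first of these sentences, 6 and 1, 6 and 5, 5 and 4 and 4 and 2 in the next, and 6 and 2, 2 and 3, 2 and 0 and 2 and 0 in the last.

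**Figure D3:**
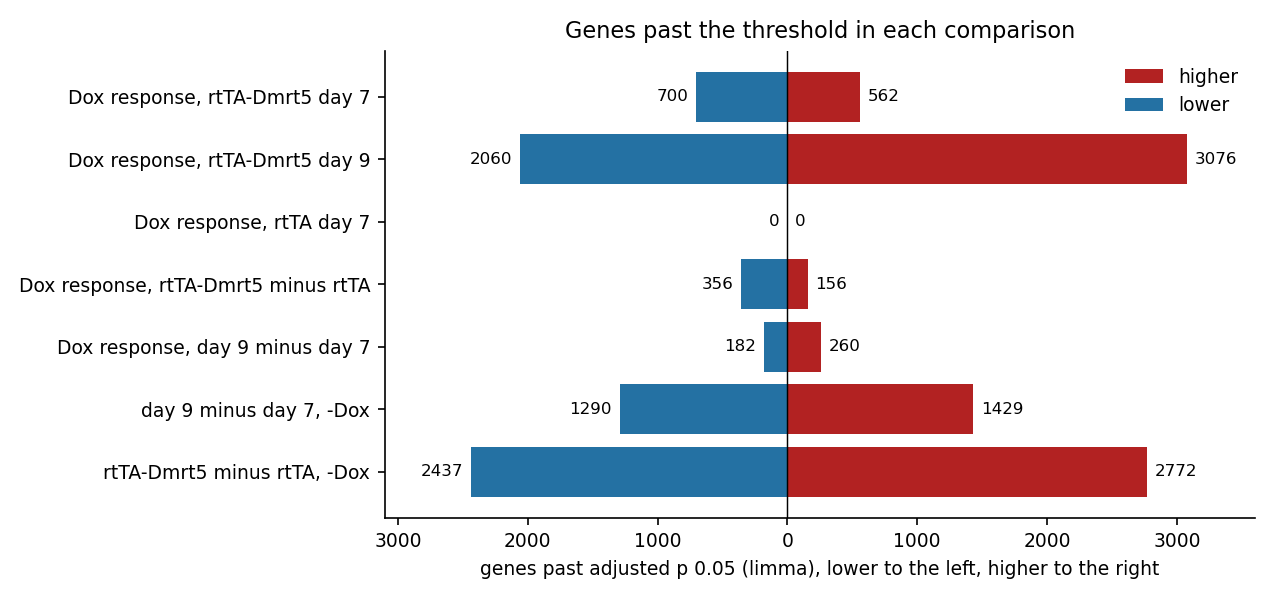
Number of genes past adjusted p 0.05 in limma (horizontal axis) in each of 7 comparisons (rows), higher to the right and lower to the left; Dox responses are arrays labelled +Dox over those labelled -Dox. The counts run from 0 in the parental line to 5209 between the lines without Dox.

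The responses at both days were then set against each other. Of the 562 genes higher at day 7, 452 were also higher at day 9, where 95.02 would be expected of independent lists, and of the 700 lower at day 7, 504 were also lower, against 79.3 expected. The comparisons share no arrays. One-sided Fisher's exact test gave p = 1.11e-250 for the higher genes and a log10 p of -332 for the lower ones, though genes are not independent replicates. Across all genes the log2 fold changes of day 7 and day 9 correlated at r = 0.65, and those of day 7 in rtTA-Dmrt5 and in rtTA at r = -0.06. Among the 956 genes shared in the same direction, the median size of the change was 0.73 at day 7 and 0.88 at day 9. A further 18 genes passed at both days in opposite directions. Olig2, a factor of ventral and oligodendrocyte progenitors, was -1.68 at day 7 and 0.92 at day 9, and the Fgf target Etv4 -0.61 and 0.98, although a dimmer probe set of Etv4 lay at -0.32 at day 9. The overlap of 956 was 495 or 432 without replicate 1 or 2 of the day 7 arrays labelled -Dox, and 508 or 421 without replicate 1 or 2 of those labelled +Dox.

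**Figure D4:**
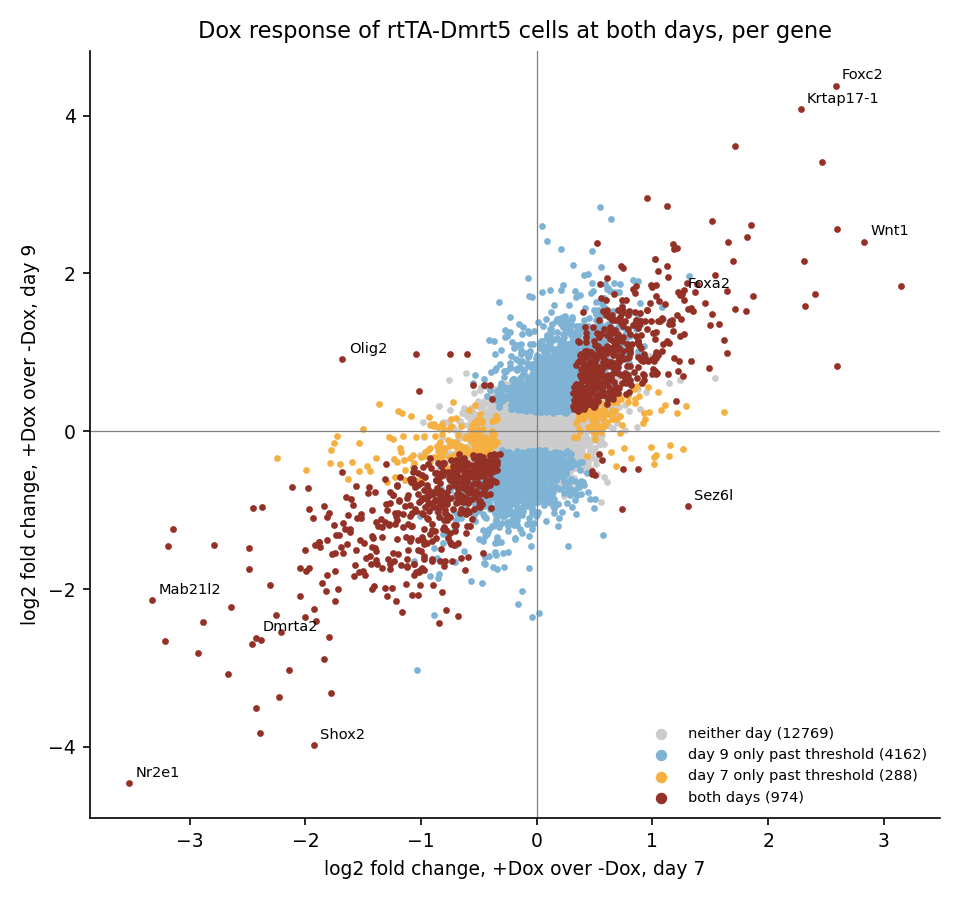
Log2 fold change of each of 18193 genes in rtTA-Dmrt5 arrays labelled +Dox over those labelled -Dox at day 7 (horizontal axis) and day 9 (vertical axis), coloured by the days at which the gene passed adjusted p 0.05. Of these, 956 passed at both days in the same direction and 18 in opposite directions.

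The difference between the Dox responses at day 9 and day 7 passed the test for 442 genes, 260 more positive and 182 more negative at day 9. Of these, 239 moved the same way at both days and further at day 9, 32 moved the same way and less far, and 171 had opposite signs. The most positive differences were in Olig2 (2.59 ± 0.28), Pla2g7 (2.56), Mcoln3 (2.32), Cntn6 (2.29), P2ry14 (2.10) and 3110039M20Rik (2.04). The most negative were in Crhbp (-2.32 ± 0.27), the calcium-binding protein gene Calb1 (-2.32), Sez6l (-2.25), Shox2 (-2.05), Lamp5 (-2.03) and 4930481B07Rik (-1.90). The day 9 change of Sez6l, -0.95, was 0.84 in 1 of its 2 probe sets. The list results that follow rest in part on the day 9 arrays labelled +Dox, which stood apart in some control values. Hybridisation spike-ins differed by -0.81 between arrays labelled +Dox and -Dox at day 9 and by -0.32 at day 7 (pooled SD 0.13). Fgf targets were more positive at day 9 as a list (4 of 12 past the threshold, 8 more positive and 1 more negative adjusted over the list alone; camera adjusted p = 2.74e-06, adjusted p = 0.105 with an estimated correlation). The same direction passed camera for cell cycle genes (adjusted p = 8.44e-05, adjusted p = 0.105 with an estimated correlation), epithelium and placode genes (adjusted p = 0.00384, adjusted p = 0.231 with an estimated correlation) and mesenchyme (adjusted p = 0.0129, adjusted p = 0.313 with an estimated correlation). Ventral-lateral midbrain and neurotransmitter genes were more negative (adjusted p = 0.00384 and 0.00848; adjusted p = 0.231 and 0.422 with an estimated correlation). Members past the threshold numbered 2, 3 and 0 in the cell cycle, epithelium and mesenchyme lists and 6, 6 and 5 adjusted over the list alone; in the 2 lists that were more negative they numbered 4 and 2, and 6 and 3 adjusted over the list alone, with 1 ventral-lateral midbrain gene more positive. The count was 84 or 141 without replicate 1 or 2 of the day 7 arrays labelled -Dox, 104 or 84 without those labelled +Dox, 116 or 203 without the day 9 arrays labelled -Dox and 221 without replicate 1 of the day 9 arrays labelled +Dox. It was 280 with the mean of all probe sets per gene and 252 when the parental arrays were left out. It ranged further, to 115 with the replicate number as a block within line and day and to 701 with a recovered level of at least 4.

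Day 9 was compared with day 7 in rtTA-Dmrt5 arrays labelled -Dox, and that these hold no induced Dmrt5 rests on the labels. Neuronal genes rose: 14 of 17 pan-neuronal genes were higher and none lower, among them Syt4 (1.97), the tau gene Mapt (1.81) and Gap43 (1.02) (camera adjusted p = 3.98e-12, adjusted p = 0.0619 with an estimated correlation; 15 adjusted over the list alone). The largest rises were in the cell adhesion gene Chl1 (3.38 ± 0.23), Cbln2 (2.88), Gad2 (2.87), Lamp5 (2.82), Shox2 (2.79) and Pcp4 (2.66). The largest falls were in Ddn (-2.80), Mylk (-2.72), Pm20d1 (-2.65), Aldh1a7 (-2.51), Bmp6 (-2.40) and Prtg (-2.22). Of 17 cell cycle genes 9 fell and none rose (adjusted p = 1.38e-07, adjusted p = 0.0412 with an estimated correlation; 11 adjusted over the list alone). Of 16 ES-cell markers 12 rose, Tdgf1 (1.52) and Pou5f1 (1.0) among them, and Tbx3 (-0.61) fell (adjusted p = 4.37e-08, adjusted p = 0.0412 with an estimated correlation; 13 and 1 adjusted over the list alone). Camera also called 8 other lists that lost the call with an estimated correlation. Ventral-lateral midbrain, neurotransmitter, hypothalamus and eye field, and immediate early genes were higher (adjusted p = 0.204, 0.204, 0.27 and 0.16 with an estimated correlation). Fgf targets, Wnt targets, epithelium and placode, and cell cycle inhibitors were lower (adjusted p = 0.178, 0.204, 0.27 and 0.0875 with an estimated correlation). In all 2719 genes passed, 1429 higher and 1290 lower at day 9. The balance was 304 to 124 at 2-fold and turned to 832 to 1070 with a recovered level of at least 8. The count was 1220 or 1445 without replicate 1 or 2 of the day 7 arrays and 1354 or 1573 without replicate 1 or 2 of the day 9 arrays.

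The lines were finally compared at day 7 in arrays labelled -Dox, and which rtTA-Dmrt5 arrays these are rests on the labels. The parental arrays were higher in genes of undifferentiated cells: 12 of 16 ES-cell markers were lower in rtTA-Dmrt5, including Pou5f1 (-3.44 ± 0.16), Dppa4 (-3.25) and Nanog (-2.42), while Klf4 (2.23) and Tbx3 (1.88) were higher there (camera adjusted p = 1.08e-08, adjusted p = 0.0466 with an estimated correlation; 13 lower and 2 higher adjusted over the list alone). The largest changes by the rule included Eras (-4.28), Dppa2 (-3.98), Zscan10 (-3.72), Pim2 (-3.72), Vrtn (-5.56) and Nkx1-2 (-3.92), lower in rtTA-Dmrt5, and S100g (6.17), Gask1b (4.02), Igfbp1 (3.98), Car4 (3.95), B4galnt2 (3.91) and F3 (3.90), higher there. Hindbrain and Hox genes (10 of 16 lower, Hoxb1 at -2.52; 13 adjusted over the list alone) and cell cycle genes (12 of 17 lower, also adjusted over the list alone) were lower in rtTA-Dmrt5 (adjusted p = 4.74e-06 and 9.22e-06; adjusted p = 0.0466 for both with an estimated correlation). Fgf targets were lower as well (10 of 12, also adjusted over the list alone; adjusted p = 4.74e-06, adjusted p = 0.0682 with an estimated correlation). Cortex genes were higher (9 of 17, with 2 lower, also adjusted over the list alone), including Fezf2 (3.42), Neurog1 (2.70) and Emx2 (1.52) (adjusted p = 0.00147, adjusted p = 0.148 with an estimated correlation), and the endoderm factor Sox17 was higher by 3.76. Pan-neuronal genes were lower (7 of 17, with 2 higher; 10 and 2 adjusted over the list alone; adjusted p = 0.00147, adjusted p = 0.303 with an estimated correlation). Cell cycle inhibitors and p53 targets were higher (8 of 14, with 1 lower; 9 and 2 adjusted over the list alone; adjusted p = 0.0102, adjusted p = 0.105 with an estimated correlation). In all 5209 genes passed, 2772 higher and 2437 lower in rtTA-Dmrt5. Which direction held more genes depended on the setting. At 2-fold 660 were higher and 262 lower. The balance turned to 1371 higher and 1651 lower with a recovered level of at least 8, and 3685 higher and 4113 lower with each probe set on its own. The count was 3152 without replicate 1 of the parental arrays, and 3471 or 3086 without replicate 1 or 2 of the rtTA-Dmrt5 arrays. The 3' minus 5' difference of Actb was -0.32 ± 0.06 (SD) in these parental arrays and 0.06 ± 0.01 (SD) in the rtTA-Dmrt5 arrays.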

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

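The tests behind the explanations below were chosen after the results were seen, except the test with split arrays, which was set before its result was seen; the comparisons between lines and between days were planned. Groups of 2 arrays are too small to test whether an array stands apart from its group.

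The Dox response differed between the lines at day 7 for 512 genes and between the days in rtTA-Dmrt5 for 442 genes in limma, by tests of the differences themselves. Of 132 genes named for a Dox response or for a difference between responses, 70 passed the first test and 44 the second. Some of them were named because they passed these same tests, so the counts do not show how common such differences are. In log2 units, rtTA-Dmrt5 minus rtTA, the positive differences between the lines were Srgn (3.27), Wnt1 (3.16), Foxc2 (3.06), Gm3764 (2.88), Defa31 (2.28), Scn11a (2.25), Pcp4 (2.19), Nepn (2.14), Hlf (2.11), Islr (2.06), Krtap17-1 (1.97), Fgf18 (1.92), Rab37 (1.89), Dab2 (1.85), Sp5 (1.72), Ddn (1.59), Aldh1a2 (1.46), En1 (1.28), Sez6l (1.18), Dlk1 (1.06), Cdon (1.03), Inhbb (1.02), Bmp7 (0.99), Stra6 (0.98), Wif1 (0.98), Zfp42 (0.97) and Notum (0.89). The negative ones were Nr2e1 (-3.96), Gm20083 (-3.40), Mab21l2 (-3.36), Wfdc1 (-3.33), Mab21l1 (-3.17), Col3a1 (-3.08), Ndnf (-2.97), Pdzph1 (-2.93), Dmrta1 (-2.84), Tfap2d (-2.77), Adgrv1 (-2.71), Otx1 (-2.65), Glra1 (-2.58), Dmrta2 (-2.52), Gsx1 (-2.51), Cartpt (-2.49), Foxn4 (-2.46), Gm38604 (-2.40), Cyp26b1 (-2.24), Ndst3 (-2.15), En2 (-2.15), Shox2 (-2.13), G630016G05Rik (-1.99), Nr2f1 (-1.97), Olig2 (-1.83), Isl1 (-1.82), Th (-1.82), Lhx2 (-1.80), Pax3 (-1.75), Dmrt1 (-1.73), Rspo2 (-1.71), Nhlh1 (-1.71), Nefm (-1.61), Dusp6 (-1.58), Dmrt3 (-1.36), Nefl (-1.24), Gbx2 (-1.17), Pou4f1 (-1.11), Sp8 (-1.06), Sfrp2 (-0.96), Emx2 (-0.88), Slit2 (-0.87) and Stmn2 (-0.85).

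Between the days, day 9 minus day 7 in log2 units, the positive differences were Olig2 (2.60), Pla2g7 (2.56), Mcoln3 (2.32), Cntn6 (2.29), P2ry14 (2.10), 3110039M20Rik (2.04), Wif1 (2.0), Wfdc1 (1.91), Ddn (1.90), Krtap17-1 (1.80), Foxc2 (1.79), Il17rd (1.78), Inhbb (1.74), Mab21l1 (1.73), Etv4 (1.59), Th (1.38), Wnt5a (1.37), Notum (1.32), Cdon (1.2), Mab21l2 (1.19), Dusp6 (1.17), Id3 (1.11), Nr2f1 (0.99), Epcam (0.96), Dmrt1 (0.89) and Cdh1 (0.76). The negative ones were Crhbp (-2.33), Calb1 (-2.32), Sez6l (-2.25), Shox2 (-2.05), Lamp5 (-2.03), 4930481B07Rik (-1.90), Defa31 (-1.77), G630016G05Rik (-1.54), Otx1 (-1.43), Gm3764 (-1.31), Syt4 (-1.17), Foxn4 (-1.14), Gm38604 (-1.08), Pou4f1 (-0.99), Crabp1 (-0.89), Lmx1b (-0.89), Gad1 (-0.88) and En1 (-0.82).

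Signals also appeared outside the named genes. Of 10092 probe sets without a single named gene, 59 passed adjusted p 0.05 in limma for the Dox response at day 7 and 628 at day 9, against 0 in the parental line; at an unadjusted p under 0.05 they numbered 888, 2099 and 499. The hybridisation spike-ins, 18 probe sets, differed by -0.814 between the day 9 arrays labelled +Dox and -Dox.

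Dmrta2, the gene of the transgene, was lower in the rtTA-Dmrt5 arrays labelled +Dox at both days. Noise of a dim probe set is argued against, since the smaller of both differences was -7.36 standard errors and the probe set's recovered level was at least 8. Exchanged labels cannot be told apart from a fall of the cell's own gene. The day 7 arrays labelled +Dox lay -0.558 from the mean of all parental arrays and those labelled -Dox 1.87 from it. The SE was 0.33 for 2 arrays against 2, and is smaller against all parental arrays. An exchange needs such an order if the probe set reads the transgene, and whether it does is not given in the sources used here. Over all genes the order was the other way: the arrays labelled -Dox lay nearer to the parental arrays labelled -Dox (root mean square difference 0.504) than those labelled +Dox did (0.539). Yet the day 7 response ran partly back towards the parental line. Its covariance with the difference between the lines without Dox was -0.0351, where shared arrays give -0.0109. With a different array in each comparison it was -0.0247. Neither measure decides whether labels were exchanged. A fall of the endogenous Dmrta2 transcript under the induced protein may also give the Dmrta2 values and stays untested.

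The day 9 Dox response ran opposite to the change from day 7 to day 9 without Dox: the covariance of their log2 fold changes across genes was -0.073 (r = -0.43), where the shared arrays give -0.0109 (r = -0.50) in 50 simulations with no effect. The shared day 9 arrays are argued against as the whole source, since the covariance was -0.0603 with a different array in each comparison. Whether a lower share of neurons raised every other cell type alike cannot be told here. The 5 lists of other cell types shifted apart (permutation p = 0.0021 over 70 genes), by means from -0.129 in neural crest to 0.984 in epithelium. Listed markers that are not expressed would stay near 0 under this explanation, and the permutation treats genes as independent replicates. Slower maturation with Dox stays open as a hypothesis. The covariance of the day 7 response with the change from day 7 to day 9 without Dox was only -0.00866 (r = -0.07). Shared arrays alone give 0.0109 (r = 0.50), so the value lay -0.0196 from what they give. A change of cell type may give the same. ES-cell markers did not show this opposite course. They rose from day 7 to day 9 without Dox (12 of 16 past the threshold, mean 0.70). They also rose in the day 9 arrays labelled +Dox (10 of 16, mean 0.63), a call that did not hold with an estimated correlation. These values argue against a slower course of the whole culture alone, which asks for opposite directions. Slower maturation of only the neural cells stays open, since it sets no direction for these markers. Slower maturation and a lower share of neurons both rest on the Dox labels, whose exchange is open.

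ES-cell markers were higher in the parental line at day 7 without Dox. Of 16 markers 12 were lower in rtTA-Dmrt5, and 2 were higher, Klf4 and Tbx3. Whether the parental cultures held more undifferentiated ES cells cannot be told apart from other differences between the lines, because these are the same markers that show the pattern. A difference in RNA quality or amplification cannot be told apart from the lines, because Actb's 3' minus 5' difference differed by 0.38 between them (pooled SD 0.0623) and each line lies in its own arrays. A difference between the clones is a biological explanation that the design names and that was not tested.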

How the results depend on the processing

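The filters on recovered level, the first level reading, the fits without parental or day 9 arrays, the robust prior without a trend and the gene list settings on level, arrays and probe sets were chosen after seeing the data; the others were planned. Of the planned ones, the filter on the array median, quantile normalization and the intensity trend were not run because centred values hold no level, and the setting with no filter became the setting used. Scanner signals over background were not analysed here, so what dim signals limit is not known.

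Counts of genes past the threshold moved by over 1.5 times as follows; the cause was not tested, except that a fold threshold lowers a count by construction. With array quality weights, which were equal within each group, the day 7 Dox response had 2355 genes. With each probe set on its own the day 9 response had 7774 probe sets. With the arrays compared alone, day 9 had 3175 and the difference between days 252, also 252 without parental arrays. That difference was 280 with the mean of all probe sets and 701 with a recovered level of at least 4. With a level of at least 8, day 9 had 2871 and the lines differed in 3022. At 2-fold the counts were 328 (day 7), 800 (day 9), 301 (difference between lines), 203 (between days), 428 (day 9 minus day 7) and 922 (lines). The first level reading gave 1153 genes at day 7 and 4922 at day 9, and centring each array on its median 1269 and 5130.

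The labels give the groups the same replicate numbers. Deviations of same-numbered arrays within a line and day correlated at 0.018, -0.048 and 0.11 across genes, so these pairs shared little variation. Between other groups the correlations ran from -0.18 to 0.19, the latter between the lines' day 7 arrays labelled +Dox. These values cannot tell whether same-numbered arrays came from the same culture or run, which the labels leave unstated. With the replicate number as a block within line and day, the parental line had 1 gene, the difference between lines 322 and that between days 115. Other counts stayed within 1.5 times, and a block over all groups moved none by that much. Leaving an array out lowers the power of a test, whichever array it is, so a lower count does not single out an array. Without single arrays, where the lone array left is assumed to vary like the other groups, the ranges were 521 to 637 (day 7), 3065 to 4659 (day 9), 0 to 1 (parental), 217 to 392 (difference between lines), 84 to 583 (between days), 1220 to 1573 (day 9 minus day 7), 3086 to 3844 (lines) and 421 to 949 (overlap).

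A named gene's value that passed in the setting used counts as unchanged if it kept direction and call. A value that did not pass also counts as unchanged if its sign turned. With arrays centred 319 were unchanged and 1 lost the call, En1 at day 9. With the mean of all probe sets 302 were unchanged, 14 lost the call and 4 gained it. With the block 303 were unchanged, 15 lost the call and 2 gained it. Without shared probe sets 310 were unchanged and 5 lost the call, and Dlk1 turned to -0.12 at day 9. Of probe sets on their own, 248 were unchanged and 80 lost the call. Turned signs are listed only for genes that passed at that day in the setting used. These turned in sign, in log2 units: at day 7 Gm3764 -0.19 (1459905_at), Inhbb -0.0675 (1426859_at), Nkx1-2 -0.13 (1426177_a_at), Dmrt3 0.0425 (1460267_at), Ntn1 -0.21 (1422987_at), Rspo2 0.050 (1430104_at), Syt1 0.25 (1421990_at), Tbx3 -0.20 (1439567_at), Tbx3 -0.0321 (1445757_at); at day 9 Gm3764 -0.21 (1459503_at), Gm3764 -0.34 (1459905_at), Sez6l 0.84 (1440128_s_at), Mylk -0.34 (1425504_at), B4galnt2 -0.27 (1439853_at), B4galnt2 -0.0551 (1441929_at), Dlk1 -0.12 (1442724_at), Dmrt3 0.10 (1460267_at), Etv4 -0.32 (1443381_at), Gata6 -0.25 (1443081_at), Sim1 -0.11 (1420736_at), Syt1 0.0252 (1421990_at), Tbx3 -0.00812 (1439567_at), Tbx3 -0.00841 (1444594_at), Tbx3 -0.0145 (1445757_at).

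The 58 list results of the day 7 and day 9 Dox responses were sorted likewise. A list past camera counts as unchanged if it kept direction and call. A list not past camera also counts as unchanged if its direction turned, as that of Fgf targets did with fry at day 7. With the block 58 were unchanged, without parental arrays 57 and with the mean of all probe sets 56. With fry 40 were unchanged. With an estimated correlation 39 were unchanged and 19 lost the call. With a recovered level of at least 4, 51 were unchanged and 4 lost the call.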

Other observations

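At day 9 members of 3 lists that did not pass camera changed in both directions in the arrays labelled +Dox. Of 10 retinoic acid pathway genes (camera adjusted p = 0.63), 4 rose and 2 fell. The transport genes Rbp4 (2.10) and Stra6 (1.85), the synthesis enzyme Aldh1a2 (1.23) and the degrading enzyme Cyp26a1 (1.10) rose, and Cyp26b1 and Crabp1 (-1.15) fell. Of 16 hindbrain and Hox genes (camera adjusted p = 0.286), 6 rose and 1 fell: Hoxb3 (1.46), Hoxb4 (1.08), Hoxb1 (1.01) and Hoxb6 (0.88) were among the rises, and the hindbrain border gene Gbx2 (-1.04) fell. Of 14 Wnt targets (camera adjusted p = 0.362, list median 0.0046), 6 rose and 4 fell; Notum (2.06) and Dkk1 (1.41) rose and Sfrp2 (-1.24) and Lef1 (-0.87) fell.

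The first principal component of the 12 arrays held 46.1% of the variance and separated the lines, with the second at 21.4% and the third at 14.7%. Parental arrays lay between -43.8 and -40.5 on the first and rtTA-Dmrt5 arrays between 15.3 and 32.8.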
